A study of Mus musculus with 12 samples.

How the data were processed

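RNA of the infarct border zone and of the matching site in sham-operated mouse hearts was measured on 12 one-colour arrays, 6 per condition. Per the labels' protocols, total RNA was extracted with Trizol, its quality was assessed on a spectrophotometer or a Bioanalyzer, and a whole-transcript expression kit was used to make biotin-labelled cDNA. The submitters' processing notes name Affymetrix Power Tools, without a version. The summary method, background correction, normalization and library files are not given in the sources used here. The deposited values are on a log2 scale, as judged from their range (1.52 to 14.37) and the nearly equal array medians. The log base is not stated, so every log2 value and fold here rests on that reading. The array medians and outer percentiles are nearly equal, as after a normalization between arrays, so a change of all genes in the same direction would not be seen in these values.

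The deposited table holds 241576 probesets. The platform annotation gave 1 gene symbol for 212097 of them, several for 4475 and none for 25004. Genes were named only from probesets with 1 symbol. Of 20416 platform symbols, 17621 were current, 2742 were updated through synonyms in a table of RefSeq genes and 53 were kept as they stood, which left 20352 genes. A gene had a median of 8 probesets, 83% of genes had 3 or more, and 2259 genes had 1. The gene-level value of an array was the median over the gene's probesets. No filter on dim signal was applied in the principal comparison, so genes at background, around 4 on the log2 scale, were tested too. Probesets of related genes can share sequence, and values of near-identical gene copies are uncertain for that reason.

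Groups and replicate numbers came from the sample titles. Both groups carry the numbers 1 to 6, and no label says that a number ties a sham heart to an infarcted one, so the groups were compared without a block. No label gives a hybridisation date or batch, and such an effect could not be examined.

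Gene-level values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. The same model was fitted to each probeset. Fold changes are infarcted minus sham on the log2 scale. They compare signals that include background, so they understate the change of genes whose signal lies near it. Every adjusted p of a gene in the text comes from this fit unless another setting is named. The 51 gene lists, written by hand before the data were examined, cover matrix, signalling, contractile, metabolic and immune genes and markers of cell types that the sample could hold. Each list with at least 5 measured members was tested with limma's camera against all other genes, with an inter-gene correlation preset at 0.01, and Benjamini-Hochberg adjustment over the lists. Members were counted as higher or lower from the gene fit, adjusted over all genes and again over the list alone. Some members of the lists were not analysed here. Unequal change of probesets within a gene was tested with limma's diffSplice (F test), leaving out probesets with a mean under the 30th percentile (5.58). Exact permutation tests of a difference between groups enumerated the 924 ways of choosing 6 of the 12 arrays. Those of a correlation within a group enumerated all orderings of its 6 arrays. Figures were drawn with matplotlib 3.10.9.

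Genes were named by a rule set before the data were examined. It took the 10 largest rises and 10 largest falls among genes past the threshold for which at least 5 of 6 infarcted arrays lay on the same side of the sham mean. From each list it took up to 3 members past the threshold with the smallest p, and the member with the smallest p in the other direction where there was any. A list with no member past the threshold gave the member with the smallest p. Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Ezh2 and Xist were named whatever their result, and the 5 genes with the smallest p for unequal probesets. Predicted genes without a name were to be given as a count only.

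The scripts were tested on simulated data made from the real means and spreads of 20352 genes, 241576 probesets or 15004 genes with several probesets. In the gene comparison, 93.9% of genes changed by 1 on the log2 scale were recovered, 58.2% of those changed by 0.5 and 5.97% of those changed by 0.25, and 4 of 20152 unchanged genes were called. In the probeset comparison, 57.6% of probesets changed by 1 were recovered, 8.96% of those changed by 0.5 and 0 of those changed by 0.25. Both simulations changed only 200 genes or probesets. Where more of them change, as in the real comparison, the adjusted threshold is less strict, so these shares are not its sensitivity. Among called real genes the smallest absolute change was 0.16 and the median 0.423. The list test recovered 5 of 5 lists shifted by 0.3 and called 0 of 43 lists without a shift, in data simulated without correlation between genes. The test of unequal probesets recovered 71.5% of 200 genes with 1 probeset changed by 1, but 43.3% of its calls were unchanged genes. With the spread made equal within each gene that share was 5.48%.

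The alternatives were the mean over probesets, removal of dim probesets or dim genes, median centring, quantile normalization, trended and robust moderation, array weights, the replicate number as a block, an unmoderated test, a threshold of 0.01, an estimated list correlation, the rotation test fry, other settings of the probeset test and the omission of each array in turn. The omission of infarcted replicates 4 and 5 together, and of probesets without exactly 1 gene symbol, was chosen after seeing the data.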

Results

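The series measured gene expression in the border zone, the heart tissue beside a myocardial infarct, in hearts of C57BL/6J mice 12 weeks of age. Tissue was taken 2 weeks after surgery from 6 infarcted hearts and, at the matching site, from 6 sham-operated hearts, which went through surgery in place of an infarct. The series text calls the 6 samples of each condition biological replicates. Its title places the mouse data in a comparison of heart injury in zebrafish and mouse that looks for repair pathways under microRNA control. The zebrafish hearts were not analysed here, so the question answered is how the mouse border zone differed from sham tissue. Each RNA was hybridised to a biotin-labelled, one-colour array, and the deposited table holds 241576 probesets, most of them covering part of a gene. The number of arrays, 6 per condition, limits the precision of every value.

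The 12 arrays had nearly equal brightness, with medians between 6.997 and 7.06 on the log2 scale. The small difference followed the groups, with sham arrays from 6.997 to 7.026 and infarcted arrays from 7.045 to 7.058. The arrays correlated with each other between 0.956 and 0.979 over all probesets. No pair of the 66 held identical values. The first principal component of the gene-level values carried 40.8% of the variance, and the sham arrays (-27.3 to -19.1) and infarcted arrays (16.0 to 31.1) did not overlap on it.

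The infarcted border zone differed from sham tissue in the expression of 4124 of 20352 genes. The largest rises were in genes of the scar matrix and its assembly. Spp1, which encodes osteopontin, rose from 4.55 ± 0.40 to 8.81 ± 0.83 (mean log2 signal ± SD, n = 6 arrays per group). The ratio of 19.2 (95% interval 11.9 to 30.8) may understate the change, since its sham signal lay near background. Lox, a collagen cross-linking enzyme, rose 13.5-fold, and the matrix proteins Fmod (fibromodulin) and Comp each rose 13.3-fold. Sfrp2, a secreted Wnt-binding protein, rose 11.8-fold and Thbs4 (thrombospondin 4) 10.7-fold. Col12a1 (9.86-fold), Timp1 (8.98-fold), Ltbp2 (8.95-fold) and Postn (periostin, 8.45-fold) completed the 10 largest rises, each with all 6 infarcted arrays above the sham mean.

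The largest falls were smaller. Inmt, a methyltransferase, fell by 1.97 on the log2 scale (3.93-fold), and Ces3, a carboxylesterase, fell by 1.78 (3.43-fold). Kcnv2, a modulatory potassium channel subunit, was 3.31-fold lower, and Scn4b, an auxiliary sodium channel subunit, was 3.13-fold lower. Pfkfb1 (2.61-fold), Mrgprh (2.56-fold), Rbfox1 (a splicing regulator, 2.37-fold), Lgals4 (2.35-fold), Pkd2l2 (2.28-fold) and Rpl3l (a striated muscle form of a ribosomal protein, 2.27-fold) made up the rest of the 10. All 6 infarcted arrays lay below the sham mean for each of them.

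Of the 4124 genes, 2050 were higher and 2074 lower in infarcted tissue (limma, adjusted p under 0.05). With each array centred on its median the split was 1748 higher and 2956 lower. Among the 280 genes that changed at least 2-fold, 260 were higher and 20 lower. The groups did not overlap in 2292 genes (11.3%), against 0.22% by chance. Leaving out infarcted replicates 4 and 5, which carried the most signal from atrial and adipocyte markers, gave 3123 genes, of which 2934 were among the 4124. Fewer arrays alone lower the count, and leaving out a single array gave as few as 3454 genes. No other pair was left out, so the loss cannot be assigned to those tissues.

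**Figure D1:**
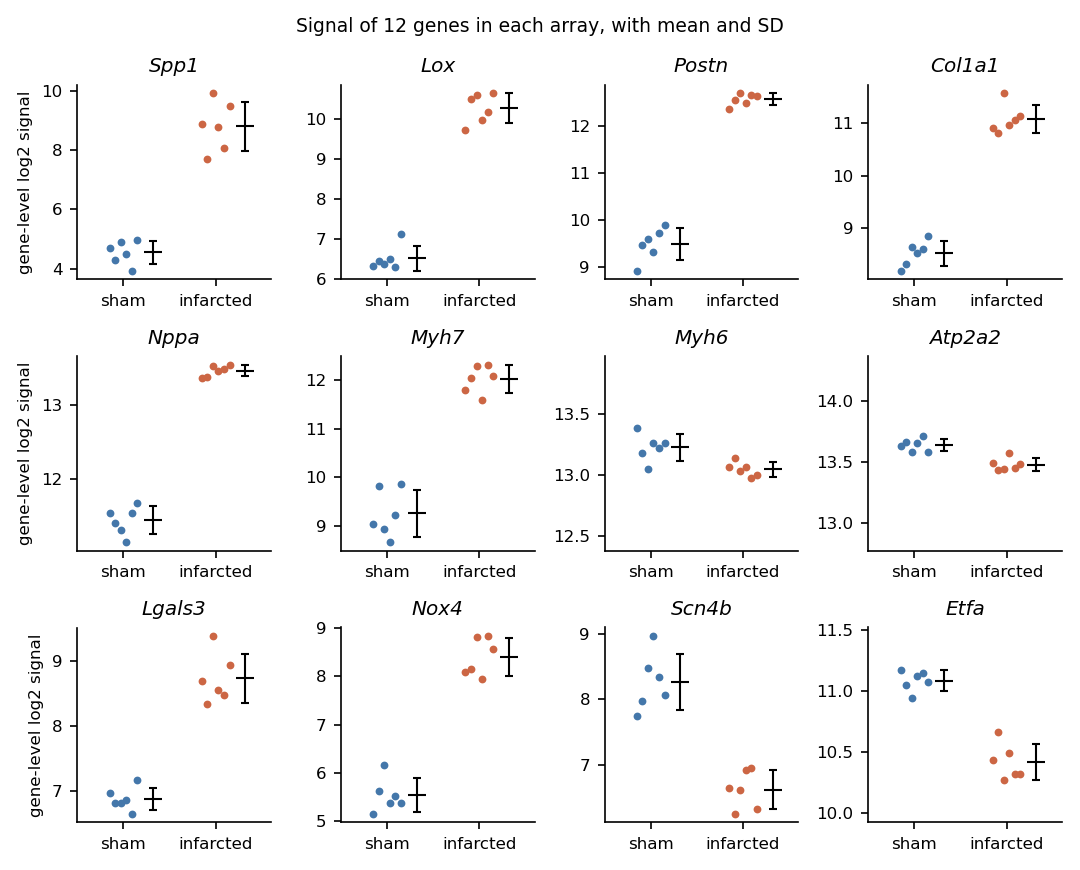
Gene-level log2 signal (vertical axes, each with its own range) of 12 genes in the 6 sham (blue) and 6 infarcted (orange) arrays, in order of replicate number within a group. Each point is an array and the black mark with bars beside them is the mean ± SD. Spp1 lies at 4.55 in sham and 8.81 in infarcted tissue, while Myh6 differs by -0.18 and Atp2a2 by -0.16.

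Genes of the extracellular matrix rose together. Of 37 matricellular proteins and matrix glycoproteins, 36 rose and none fell (37 rose adjusted over the list alone), with a median change of 1.84. Ltbp2 (3.16), Thbs4 (3.43) and Fmod (3.74) had the smallest p of that group. Of 29 collagens and cross-linking enzymes, 24 rose and none fell (25 rose adjusted over the list alone). Col1a1 and Col3a1, the main fibrillar collagens of scar tissue, rose by 2.55 and 2.07, from 8.52 ± 0.24 to 11.07 ± 0.27 and from 8.07 ± 0.20 to 10.14 ± 0.31 (SD, n = 6). Of 26 matrix proteases and inhibitors, 15 rose and 1 fell (19 and 1 adjusted over the list alone). The collagen-degrading enzymes Ctsk (cathepsin K) and Mmp2 rose by 1.76 and 1.69, alongside the inhibitor Timp1. Timp4, another inhibitor, was the member that fell (-0.88, adjusted p = 0.0306), a call that ended in 7 of the 12 fits with an array left out (adjusted p up to 0.0703). Each of the 3 lists was higher than the other genes with a preset correlation (camera, adjusted p = 6.55e-53, 3.14e-33 and 6.03e-15) and with an estimated correlation (adjusted p = 0.0154 for each).

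Markers of fibroblasts and of the pathways that act on them were also higher. Of 18 fibroblast markers, 15 rose and none fell (16 rose and 1 fell adjusted over the list alone), led by Mfap5 (2.37), Col1a1 and Col1a2 (2.04). Of 15 genes of contractile myofibroblasts, 11 rose (12 adjusted over the list alone). Runx1 and Meox1, both transcription factors, rose by 2.06 and 1.69, and the actin cross-linker Actn1 by 1.13. In the TGF-beta and BMP pathway, 19 of 34 genes rose and 1 fell (22 and 1 adjusted over the list alone). Examples were Ltbp2, Fstl1 (2.29) and Ccn2 (connective tissue growth factor, 2.03), while the co-receptor Tgfbr3 fell by 0.35. Of 44 genes of the Notch, Wnt and Hippo pathways, 19 rose and 2 fell (19 and 5 adjusted over the list alone). The strongest were the secreted Wnt antagonists Frzb (2.68), Sfrp2 (3.56) and Sfrp1 (1.81), and the neuregulin receptor Erbb4 fell by 0.38. These 4 lists were called with the preset correlation (adjusted p = 1.69e-17, 2.08e-11, 7.63e-13 and 6.91e-07) and with the estimated one (adjusted p = 0.021 for each).

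**Figure D2:**
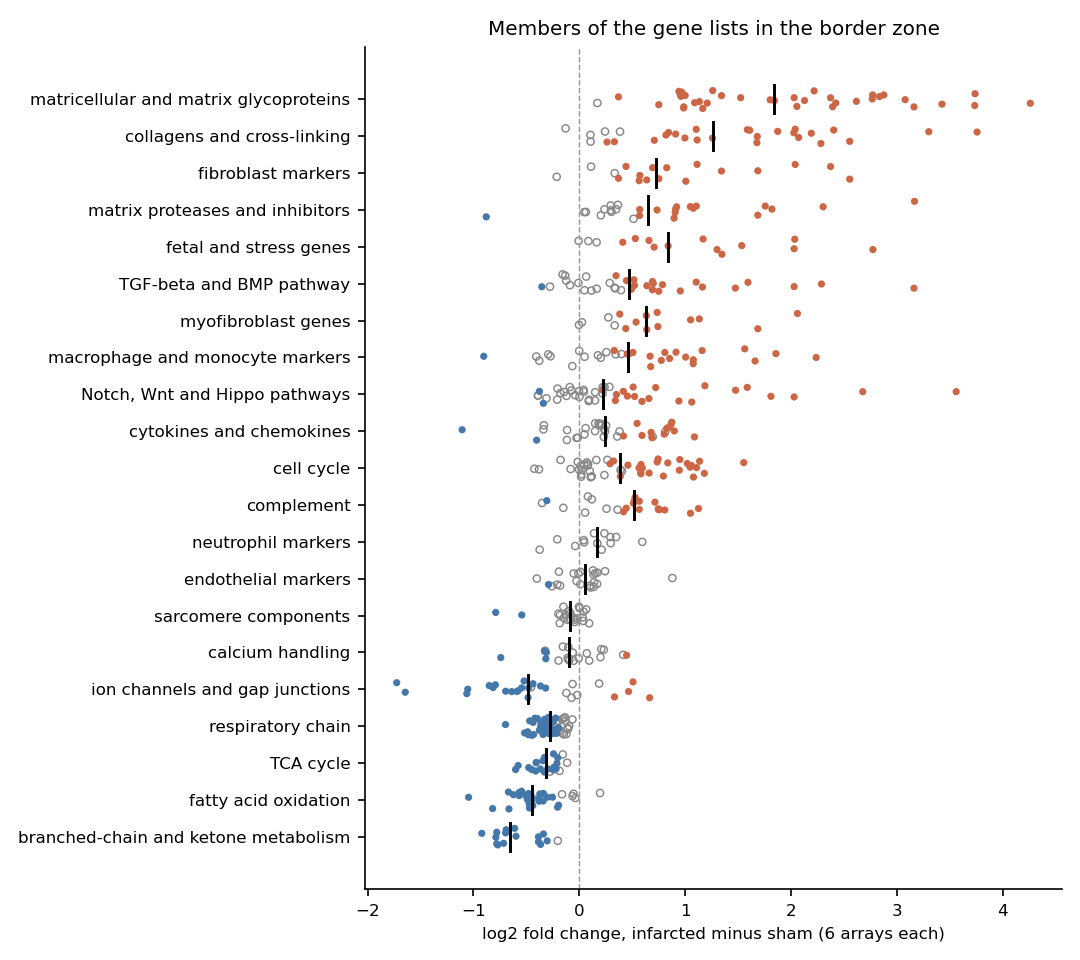
Log2 fold change, infarcted minus sham (horizontal axis), of each measured member of 21 gene lists (vertical axis). A point is a gene, filled orange or blue where it was higher or lower past the threshold and open where it was not, and a black bar is the list's median, 1.84 for matricellular proteins and -0.45 for fatty acid oxidation.

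The fetal and stress genes of cardiomyocytes were higher. Of 15 members, 12 rose and none fell (13 rose adjusted over the list alone; camera adjusted p = 8.02e-15, and adjusted p = 0.0164 with an estimated correlation). The natriuretic peptide genes Nppa and Nppb rose by 2.04 (4.1-fold) and 1.30 (2.46-fold). Myh7, the slow myosin heavy chain of the fetal mouse ventricle, rose 6.83-fold, from 9.25 ± 0.49 to 12.03 ± 0.28 (SD, n = 6), and Acta1, skeletal alpha-actin, 2.9-fold. Myh6, the adult fast myosin heavy chain, differed by -0.18 (adjusted p = 0.0688), and Atp2a2, the calcium pump of the sarcoplasmic reticulum, by -0.16 (adjusted p = 0.0704), with all 6 infarcted arrays below the sham mean in each. Both passed when the gene value was the mean in place of the median over probesets (adjusted p = 0.0166 and 0.00438), and in 3 other settings, and Myh6 passed without sham replicate 3 (adjusted p = 0.0339, up to 0.143 without another array). These are bright genes, at 13.23 and 13.63 in sham hearts, near the top of the measured range of 14.37.

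Sarcomere components as a list did not pass (adjusted p = 0.107, and adjusted p = 0.396 with an estimated correlation), with a median of -0.09. A small fall was seen all the same. The list's mean deviation lay between -0.191 and -0.0709 in infarcted arrays and between -0.021 and 0.0384 in sham arrays. The rotation test fry, which does not compare a list with other genes, called it lower (adjusted p = 0.00256). Of 24 genes 2 fell and none rose, also adjusted over the list alone. They were Tcap, the telethonin gene of the Z-disc (-0.79), and Cmya5 (-0.54).

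Genes of mitochondrial fuel use were lower. In fatty acid oxidation 27 of 32 genes fell and none rose (27 fell adjusted over the list alone), with a median of -0.45. Etfa, which passes electrons from acyl-CoA dehydrogenases to the respiratory chain, fell by 0.67, from 11.08 ± 0.08 to 10.41 ± 0.14 (SD, n = 6), Cpt2, of the carnitine shuttle, by 0.57, and Acot2 by 0.57. Among genes of branched-chain amino acid and ketone breakdown, 15 of 16 fell (15 adjusted over the list alone), with a median of -0.65, among them Bckdha (-0.77), Bcat2 (-0.69) and Dbt (-0.79). Of 59 respiratory chain genes 44 fell and none rose (52 fell adjusted over the list alone), with a median of -0.28, for example Ndufb3 (-0.47), Ndufs3 (-0.43) and Ndufa5 (-0.52). Of 22 genes of the TCA cycle 18 fell (21 adjusted over the list alone), including Sdha (-0.45), Fh1 (-0.41) and Suclg2 (-0.60). These 4 lists were lower than other genes with the preset correlation (adjusted p = 5.08e-14, 6.5e-13, 4.93e-17 and 1.9e-10) but not with the estimated one (adjusted p = 0.106, 0.0736, 0.14 and 0.142). The counts of single genes do not depend on that choice. Members of these lists moved together, with estimated correlations from 0.4 to 0.47, so the genes counted are not independent of each other.

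**Figure D3:**
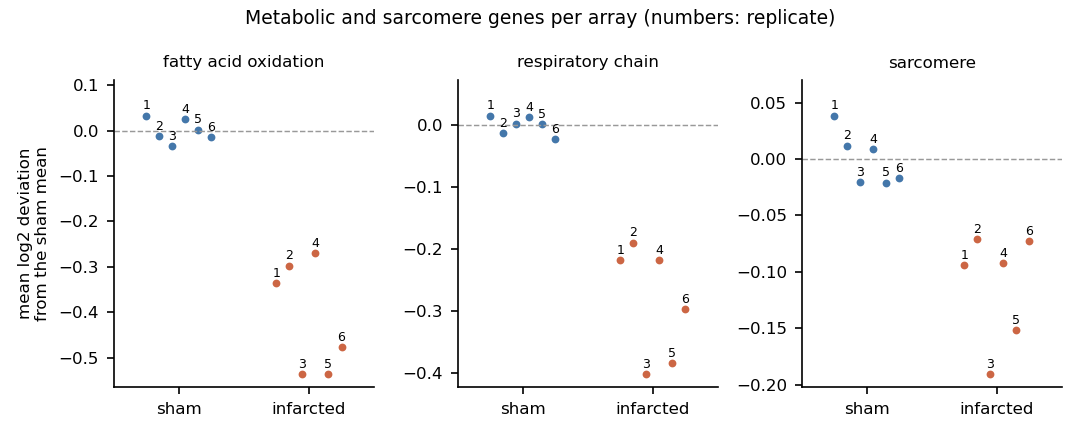
Mean deviation from the sham mean, in log2 units (vertical axes, each with its own range), of the fatty acid oxidation, respiratory chain and sarcomere genes in each array, numbered by replicate within sham (blue) and infarcted (orange). The infarcted arrays lie between -0.54 and -0.27 for fatty acid oxidation, between -0.40 and -0.19 for the respiratory chain and between -0.19 and -0.07 for the sarcomere.

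Other energy genes moved both ways. For creatine and energy transfer, 7 of 14 genes fell and 1 rose (7 and 1 adjusted over the list alone). Mpc2, of the mitochondrial pyruvate carrier, fell by 0.73, Vdac3 by 0.22, and Ckb, the brain form of creatine kinase, rose by 0.37. The list passed narrowly (adjusted p = 0.0426, and adjusted p = 0.442 with an estimated correlation), and its call ended in 6 of the 12 fits with an array left out (adjusted p up to 0.0732). Of 24 glycolysis and glucose uptake genes 5 rose and 7 fell (6 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.575). The platelet form of phosphofructokinase, Pfkp, rose by 1.21, while Pfkfb1 fell by 1.38 and Ldhb by 0.54.

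Of 28 ion channel and gap junction genes, 18 fell and 4 rose (18 and 5 adjusted over the list alone), with a median of -0.48 (adjusted p = 3.38e-06, and adjusted p = 0.106 with an estimated correlation). Kcnv2 fell by 1.72, Scn4b by 1.64 and the potassium channel subunit Abcc9 by 0.58, and the sodium channel gene Scn7a rose by 0.51. Of 21 calcium-handling genes 4 fell and 1 rose (6 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.413). Hrc, a calcium-binding protein of the sarcoplasmic reticulum, fell by 0.74, Cacna2d1 by 0.32 and Trdn (triadin) by 0.31. Fkbp1b rose by 0.45 (adjusted p = 0.0468), but its call ended in 9 of the 12 fits with an array left out (adjusted p up to 0.0991) and in 5 other settings. Its value was -0.13 with dim probesets left out (adjusted p = 0.503), and there Trdn did not pass either (adjusted p = 0.331). Of 12 conduction system markers Hcn4, a pacemaker channel, fell by 0.52 and Gja5, a gap junction gene, rose by 0.47 (1 and 1 also adjusted over the list alone; list adjusted p = 0.608). Among 22 cardiac transcription factors 6 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 0.0426, and adjusted p = 0.241 with an estimated correlation), and the list's call ended in 5 of the 12 fits with an array left out (adjusted p up to 0.0709). Hopx (-0.66) and Tbx5 (-0.68) fell, and Tbx20 rose by 0.61. Of 16 adrenergic and neurohumoral genes 3 rose and 3 fell (6 and 4 adjusted over the list alone; list adjusted p = 0.858), with a negative median (-0.08) and a positive mean (0.08). The angiotensin-converting enzyme Ace rose by 1.01, the angiotensin receptor Agtr1a fell by 0.64, and Corin, a protease that processes natriuretic peptides, fell by 0.44.

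Some immune lists were higher, among them macrophage and monocyte markers. Of 31 macrophage and monocyte markers 18 rose and 1 fell (19 and 3 adjusted over the list alone; camera adjusted p = 1.96e-09, and adjusted p = 0.021 with an estimated correlation). Lgals3, which encodes galectin-3, rose 3.62-fold, Mpeg1 3.16-fold and Tyrobp 2.11-fold, and Retnla fell by 0.90. Of 36 cytokine and chemokine genes 12 rose and 2 fell (13 and 3 adjusted over the list alone; adjusted p = 0.000105, and adjusted p = 0.0303 with an estimated correlation). Cxcl16 rose by 0.83 and Cx3cl1 by 0.84, and the eosinophil attractant Ccl11 fell by 1.11. Of 22 complement genes 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 7.34e-07, and adjusted p = 0.106 with an estimated correlation), with C1qb (0.75), Itgam (0.81) and Serping1 (0.71) higher and Cd59a lower (-0.31). Of 16 antigen presentation genes 4 rose (8 adjusted over the list alone; adjusted p = 0.000165, and adjusted p = 0.267 with an estimated correlation), among them Cd80 (0.75), the class II gene H2-Aa (0.57) and B2m (0.30, adjusted p = 0.0287). The call for B2m ended in 8 of the 12 fits with an array left out (adjusted p up to 0.0643), with the mean over probesets (0.19, adjusted p = 0.0795) and with arrays centred on their medians (adjusted p = 0.0535).

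Other immune lists did not pass. In sham hearts the median signal was 4.36 for neutrophil and 5.14 for T and NK cell markers. It was 5.41 for B cell and 5.11 for mast and dendritic cell markers, against 7.3 for interferon response genes. Such dim signal limits what the cell marker lists can show, so their results do not exclude a change. Of 13 neutrophil markers none passed in limma, also adjusted over the list alone, and 2 had an unadjusted p under 0.05. The smallest p was that of Mpo (-0.37, adjusted p = 0.0614), which passed with sham replicate 2 or 3 left out (adjusted p from 0.0224 to 0.128 over the 12 fits), with arrays centred on their medians (adjusted p = 0.0365) and with quantile normalization (adjusted p = 0.0417). The list's adjusted p was 0.325. Of 20 T and NK cell markers Cd28 fell by 0.81 and Il7r rose by 0.78 (1 and 1 also adjusted over the list alone; list adjusted p = 0.452), but with dim probesets left out Il7r differed by 0.14 and did not pass (adjusted p = 0.559). Of 12 B cell markers Cd79b rose by 0.54 (1 also adjusted over the list alone; list adjusted p = 0.157). Of 14 mast and dendritic cell markers Cd209a (0.83), Itgax (1.05, from a sham signal near background, 4.98) and Kit (0.70) rose. Adjusted over the list alone 3 rose, and the list's adjusted p was 0.157. Of 28 interferon response genes Ifit2 (0.53), Oasl2 (0.35) and Irf7 (0.45) rose (3 adjusted over the list alone; list adjusted p = 0.133). The calls for Oasl2 and Irf7 ended in 6 and 5 of the 12 fits with an array left out, and the list passed without infarcted replicate 2 (adjusted p = 0.0153, up to 0.24 without another array).

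Cell cycle genes were higher: 24 of 46 rose and none fell (26 rose and 2 fell adjusted over the list alone; camera adjusted p = 9.78e-11, and adjusted p = 0.0806 with an estimated correlation). Anln, of the cleavage furrow, rose 2.93-fold from a sham signal near background (4.74), the mitotic kinase gene Cdk1 2.15-fold and Rrm2, of nucleotide synthesis, 1.93-fold. Of 18 cell cycle inhibitor and senescence genes 2 rose and 3 fell (4 and 3 adjusted over the list alone; list adjusted p = 0.506), among them Btg1 (0.46), Rbl2 (-0.34) and Cdkn1c (-0.43). Of 23 immediate early genes 5 rose (5 adjusted over the list alone; adjusted p = 0.00217, and adjusted p = 0.42 with an estimated correlation), for example Ccn1 (0.94), Egr2 (1.10) and Myc (0.68).

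Of 22 endothelial markers Aqp1, a water channel, was the member that passed (-0.29, adjusted p = 0.024; none passed adjusted over the list alone), and that call ended in 4 of the 12 fits with an array left out. The list's adjusted p was 0.521, and its mean of 0.03 turned to -0.01 with arrays centred on their medians. Of 28 hypoxia and angiogenesis genes 7 rose and 3 fell (7 and 4 adjusted over the list alone, list adjusted p = 0.153). Hif1a (0.58), Car9 (0.55, from a sham signal near background, 4.86) and Pdgfc (0.57) were higher and Vegfb was lower (-0.34). Of 18 smooth muscle and pericyte markers 7 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.241 with an estimated correlation). The contractile genes Tagln (0.74) and Cnn1 (1.05) rose and Abcc9 fell. Of 8 lymphatic markers 4 rose and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.0389, and adjusted p = 0.106 with an estimated correlation). Pdpn (1.15), also found on activated fibroblasts, and Fgl2 (0.66) rose, while Prox1, the lymphatic transcription factor, fell by 0.41. That list's call ended without infarcted replicate 2 (adjusted p = 0.0633) and without sham replicate 5 (adjusted p = 0.0662). Of 11 endocardial and valve markers 6 rose (6 adjusted over the list alone; adjusted p = 2.31e-06, and adjusted p = 0.0279 with an estimated correlation). They included the tendon and valve matrix genes Fmod (3.74) and Tnmd (1.35, from a sham signal near background, 4.82), and Plvap (1.47).

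Markers of neighbouring tissues differed between single infarcted arrays. The mean deviation of 15 adipocyte markers from the sham mean was 1.67 in infarcted replicate 5 and between -0.02 and 0.55 in the other infarcted arrays. Of those markers 1 rose and 1 fell (1 and 1 adjusted over the list alone), and the list missed the threshold (adjusted p = 0.0501, and adjusted p = 0.54 with an estimated correlation). It passed in 5 of the 12 fits with an array left out (adjusted p from 0.0125 to 0.239 over the 12), and without infarcted replicate 5 its mean went from 0.49 to 0.25 (adjusted p = 0.239). Dio2, a deiodinase that activates thyroid hormone, rose 4.32-fold between the group means, with all 6 infarcted arrays above the sham mean, and the lipase gene Lipe fell by 0.36. Of 18 epicardial and mesothelial markers 5 rose (5 adjusted over the list alone; adjusted p = 0.00187, and adjusted p = 0.241 with an estimated correlation), with Tcf21 (1.01), Krt18 (0.82) and Tbx18 (0.47) leading. Replicate 5 again had the highest mean, 0.81, and without it the mean over infarcted arrays went from 0.30 to 0.19 (adjusted p = 0.0246). Of 18 skeletal muscle markers Acta1 rose and Ckm fell by 0.32 (1 rose and none fell adjusted over the list alone; list adjusted p = 0.661), and replicate 5 had a mean of 0.70, without which that of the infarcted arrays went from 0.12 to 0.00494. The call for Ckm ended in 8 of the 12 fits with an array left out (adjusted p up to 0.0798) and with dim probesets left out (-0.19, adjusted p = 0.0612). Of 14 atrial markers 5 rose and 2 fell (5 and 2 adjusted over the list alone; adjusted p = 0.0389, and adjusted p = 0.278 with an estimated correlation). Nppa and Dkk3 (1.59) rose and Kcnj3, of the atrial acetylcholine-gated channel, fell by 1.06. The atrial mean was 0.997 in infarcted replicate 4, and the list did not pass without that array (adjusted p = 0.14), nor without sham replicate 3 (adjusted p = 0.0544) or sham replicate 5 (adjusted p = 0.0565).

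**Figure D4:**
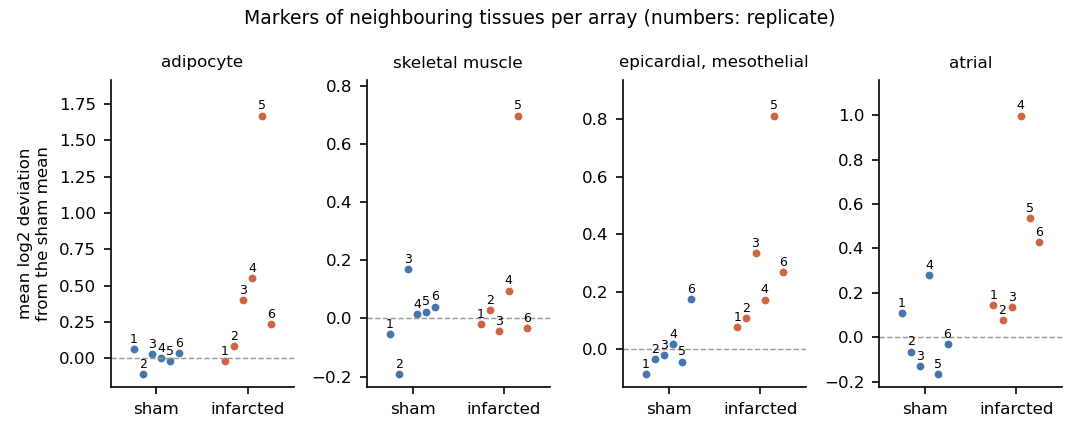
Mean deviation from the sham mean, in log2 units (vertical axes, each with its own range), of adipocyte, skeletal muscle, epicardial and mesothelial, and atrial markers in each array, numbered by replicate within sham (blue) and infarcted (orange). Infarcted replicate 5 lies highest for adipocyte (1.67), skeletal muscle (0.70) and epicardial markers (0.81), and infarcted replicate 4 for atrial markers (0.997).

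The series title names microRNA-dependent repair. Genes of the microRNA machinery differed little, but their transcripts do not measure microRNAs or the effect of these on targets. Of 16 such genes Dgcr8 rose by 0.24, and Ago4 (-0.29) and Tarbp2 (-0.27) fell (none passed adjusted over the list alone; list adjusted p = 0.634). Their calls ended in 9, 6 and 10 of the 12 fits with an array left out. That for Dgcr8 also ended with array weights (adjusted p = 0.055), centring (adjusted p = 0.0804) and quantile normalization (adjusted p = 0.0776), and that for Tarbp2 with the mean over probesets (adjusted p = 0.0727). Of 11 Polycomb repressive complex 2 genes Jarid2 fell by 0.34 (1 also adjusted over the list alone; list adjusted p = 0.521). Ezh2, its methyltransferase, differed by 0.10 (adjusted p = 0.587), and passed with the mean over probesets (adjusted p = 0.0274). Of 17 circadian clock genes 1 rose and 5 fell (2 and 6 adjusted over the list alone; list adjusted p = 0.249). The output genes Hlf (-0.81), Ciart (-0.91) and Dbp (-0.40) fell, and the call for Arntl (0.63, adjusted p = 0.0488) ended in 11 of the 12 fits with an array left out. It also ended with dim probesets left out (adjusted p = 0.139), with arrays centred on their medians (adjusted p = 0.0596), with the mean over probesets (adjusted p = 0.0561) and with quantile normalization (adjusted p = 0.0627). The hour of tissue collection is not given in the sources used here.

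Of 28 antioxidant and redox genes 7 rose and 8 fell (10 and 11 adjusted over the list alone; list adjusted p = 0.548), with a negative median (-0.04) and a positive mean (0.15). Nox4, a hydrogen peroxide-producing oxidase, rose 7.33-fold, Gpx3 by 0.75 and Sod3 by 0.58, and the peroxiredoxin gene Prdx2 fell by 0.46. Of 22 unfolded protein and heat shock genes 2 rose and 3 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.97). The endoplasmic reticulum genes Herpud1 (-0.77) and Hspa5 (-0.30) fell, and Pdia4 rose by 0.23, a call that ended in 5 of the 12 fits with an array left out and with arrays centred on their medians (adjusted p = 0.0631). Of 38 ribosomal protein genes 5 rose and 1 fell (4 and 0 adjusted over the list alone; list adjusted p = 0.287). Rpl12 (0.70), Rpl3 (0.67) and Rpl26 (0.37) rose, and Rps23 (-0.34) fell. The call for Rps23 ended in 10 of the 12 fits with an array left out and that for Rpl26 without infarcted replicate 6 (adjusted p = 0.052). With the mean over probesets Rpl26 differed by 0.08 (adjusted p = 0.302), and Rpl12 rose by 0.34.

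The remaining lists held markers of cells and sites outside the muscle. Of 13 Schwann cell and neuronal markers Uchl1 rose 2-fold, and Kcna1 (-0.66) and Gfra3 (-0.36) fell (1 and 2 adjusted over the list alone; list adjusted p = 0.995). Of 10 erythroid and platelet markers Alas2 (-0.49) and Gp9 (-0.44) fell (3 adjusted over the list alone; list adjusted p = 0.2). Of 14 markers of lung and other thoracic tissue Scgb3a2 fell by 0.39 (none adjusted over the list alone; list adjusted p = 0.413). The calls for Gfra3, Alas2, Gp9 and Scgb3a2 ended in 5, 7, 8 and 5 of the 12 fits with an array left out. Gp9 differed by -0.14 with the mean over probesets (adjusted p = 0.106) and by -0.21 with dim probesets left out (adjusted p = 0.0563), and Scgb3a2 by -0.18 with the mean (adjusted p = 0.0445). None of 6 sex-linked genes passed in limma, also adjusted over the list alone, and 1 had an unadjusted p under 0.05 (list adjusted p = 0.652). The Y-linked gene Uty stood at 8.60 ± 0.19 in sham and 8.40 ± 0.09 in infarcted hearts (SD, n = 6), and Xist, which is expressed from the inactive X chromosome, at 3.77 ± 0.12 and 3.62 ± 0.09.

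Over all 51 lists, camera with a preset correlation called 26, 19 of them higher and 7 lower in infarcted tissue. That number was not larger than other groupings of the arrays can give: 6 of 100 splits of the 12 arrays, the real one included, gave at least 26 lists. The other splits among the 6 kept 4 or 5 sham arrays together and so held part of the real difference. Splits with 3 sham arrays on each side gave at most 12. With the correlation estimated for each list 11 lists were called, all of them higher, and no other split of the 100 gave more than 1. The 11 are not separate findings, since Fmod, Ltbp2, Col1a1 and Ccn2, among others, are each on more than 1 of them. Lists near the threshold moved with the setting: sarcomere components and adipocyte markers passed with arrays centred on their medians (adjusted p = 0.0453 and 0.0257), and cardiac transcription factors did not (adjusted p = 0.0512). With dim genes left out, the calls ended for smooth muscle and pericyte markers (adjusted p = 0.0586), lymphatic markers (adjusted p = 0.126), atrial markers (adjusted p = 0.125) and creatine and energy transfer (adjusted p = 0.0586). With dim probesets left out before the summary, the same 4 calls ended (adjusted p = 0.0817, 0.0796, 0.106 and 0.0771). Quantile normalization ended those for cardiac transcription factors (adjusted p = 0.0594) and creatine and energy transfer (adjusted p = 0.0715), and adipocyte markers passed there (adjusted p = 0.0329). Trended and robust moderation brought sarcomere components and adipocyte markers past the threshold (adjusted p = 0.0442 and 0.0486). Without infarcted replicates 4 and 5 the calls ended for atrial markers (adjusted p = 0.248), cardiac transcription factors (adjusted p = 0.0633) and creatine and energy transfer (adjusted p = 0.0633).

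The summary over probesets mattered for some named genes. Of those past the threshold, 16 moved by over 1.5 times with the mean over probesets or with dim probesets left out, and 9 of the 16 still passed in these settings. They were Cd80, which rose by 1.23 with dim probesets left out, Kit (0.46 there), Kcna1 (-0.41 there and -0.38 with the mean), Prdx2 (-0.29 and -0.26) and Rpl12 (0.36 and 0.34), and with the mean Hlf (-0.51), Jarid2 (-0.22), Ndufb3 (-0.30) and Scgb3a2 (-0.18). Without infarcted replicates 4 and 5, 14 named genes lost their call, among them Aqp1 (adjusted p = 0.0786), Gfra3 (adjusted p = 0.0692), Irf7 (adjusted p = 0.114), Oasl2 (adjusted p = 0.128), Rps23 (adjusted p = 0.214) and Rpl26 (adjusted p = 0.091). Fewer arrays alone could end such calls.

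At the level of the deposited probesets, without any summary per gene, 25835 of 241576 passed, 15440 higher and 10395 lower. With each array centred on its median the split was 13422 higher and 14355 lower. Without infarcted replicates 4 and 5, 16744 probesets passed.

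Within genes, probesets can change unequally, as they do when exons are used differently or when some probesets respond poorly. Of 15004 genes tested 1401 passed for unequal change, and 899 of them were also among the 4124 changed genes. The 5 genes with the smallest p were all matrix or myosin genes. Col12a1 had 52 probesets with changes from 0.09 to 5.46, and Col5a1 had 58 with changes from -0.34 to 2.68. Myh7 had 33 probesets (-0.54 to 3.62), Ltbp2 had 35 (0.47 to 4.91) and Col11a1, a minor fibrillar collagen, 42 (-0.61 to 4.54), with a median change of 0.145 and 29 of the 42 higher. The test called too many genes on simulated data in which probesets of a gene differed in spread. There, with only 200 genes changed, it called 0.74% of the unchanged genes, which made up 43.3% of its calls. The share of false calls among the 1401 cannot be read from that figure. Without infarcted replicates 4 and 5 it called 891 genes.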

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

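The comparison of splits for the number of lists with an estimated correlation, the comparisons of metabolic with sarcomere genes, the first count of adipocyte markers and the correlation of a probeset's rise with its sham signal were chosen only after the results were seen. The second list of adipocyte genes was written after the first had been seen, before the values of its own members were.

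Among 414 sets of 6 arrays (each named gene and each list in each group), 19 held an array far from the other 5, where chance gives about 20.7. The gap to the nearest other array, as a share of the whole range, was above the 95% critical value of Dixon's test for 6 samples in each. Of the lists in infarcted hearts, adipocyte (0.661), epicardial and mesothelial (0.649) and skeletal muscle markers (0.812) were set apart by a high replicate 5, neutrophil markers (0.664) by a high replicate 4, the interferon response (0.691) by a low replicate 2 and conduction markers (0.733) by a low replicate 6. In sham hearts antigen presentation (0.669) had a low replicate 1 and clock genes (0.648) a high replicate 4. Of single genes in infarcted hearts, Fmod (0.672) was low in replicate 2, Cacna2d1 (0.675) and Ckm (0.844) in replicate 3 and Actn1 (0.697) in replicate 1, and Tnmd (0.642) was high in replicate 1. Of those in sham hearts, Lox (0.759) and Retnla (0.661) were high in replicate 6, Cdkn1c (0.714) and Rpl12 (0.676) were high in replicate 3, Col1a2 (0.633) was low in replicate 1 and Rps23 (0.693) low in replicate 2.

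Leaving out Dio2, 9 of 14 adipocyte markers were higher in infarcted replicate 5 than in each of the other 11 arrays, a count that restates how that array was noticed. Of the 9 the brightest were Car3 at 11.1 (up to 7.90 elsewhere), Cfd at 9.07 (up to 6.94) and Cidec at 8.16 (up to 6.46), and of the 14 markers 2 (Lipe and Cidea) had a sham mean above 8 and 1 is on another list. Fat carried along with that tissue piece may account for them. Of 20 adipocyte genes on none of the 51 lists, 11 of which had a sham mean above 8, 6 were highest in that array, against up to 4 in any other. These 6 included Cyp2e1 at 9.77 (up to 6.72 elsewhere) and Scd1 at 10.2 (up to 9.51). Dgat2, Agpat2, Aqp7 and Plin4, with sham means from 9.95 to 12.1, were not highest there and lay below those means (Aqp7 at 9.85 against 10.6). Such bright genes may leave little room to show added fat. Dimmer members were not highest there either, among them Thrsp at 7.72 (up to 8.38 elsewhere), Pnpla3 at 6.04 (up to 6.31) and Orm1 at 4.78 (up to 4.96). Adipose tissue in that sample was not settled. No biological explanation was tested, fat forming inside the injured wall stays open, and 11 of 18 skeletal muscle markers were also highest in that array.

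Fatty acid oxidation genes fell more than sarcomere genes, although cardiomyocytes express both. A lower share of cardiomyocyte RNA could lower both alike, but the mean of the 32 fatty acid oxidation genes minus that of the 24 sarcomere genes was -0.296 in infarcted against sham arrays (exact permutation p = 0.0022, two-sided, the smallest that 6 against 6 allows), with all 6 infarcted arrays below the sham range. Compression of the brightest signals could hide a fall of sarcomere genes, but among members with sham signals from 10.01 to 12.49 (20 and 11 genes) the difference was -0.211 (exact permutation p = 0.0022). In that window the sarcomere mean was -0.182, against -0.112 over all 24 genes, the direction that compression predicts. The differences of -0.296 and -0.211 argue against either of these alone as the whole cause. A part played by either, or by both together, stays open. That infarcted border zone cardiomyocytes hold less transcript for fat oxidation relative to sarcomere transcripts is a hypothesis, found and tested on the same arrays, and it stands beside a change in other cell types that use fat.

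Genes with unequal probesets were most frequent among genes that changed most, 66.8% of 274 genes with a change of at least 1 on the log2 scale against 4.43% of 10174 genes with a change under 0.25. Probesets near background that do not follow a rising gene might produce this, and would make probesets with more sham signal rise more. With no filter on dim probesets, over 158 called genes that rose at least 2-fold and had 5 or more of them, the median rank correlation within a gene of a probeset's rise over sham replicates 1 to 3 with its signal in sham replicates 4 to 6 was -0.12, with 54 genes above 0. It was -0.23 among probesets whose signal in sham replicates 4 to 6 was at least 5.58 (40 of 140 genes above 0), and -0.30 among the tested probesets, which had been filtered on a mean that includes the rise. All 3 medians lie on the side that explanation does not predict, but many genes lie on the other, and 477 of the 2895 probesets of the first comparison were not in the test, so it stays open, as do exon use, probesets with signal from other transcripts and compression of bright probesets.

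The 12 arrays were regrouped into 100 of the 462 possible splits, the real one included. For 5 of the 6 counts the real split gave the most, which a random grouping would rarely do. The other splits mix sham and infarcted arrays, so their counts do not measure how many calls are false. A batch that followed the groups could not be excluded this way. For genes 1 split, the real one, gave as many as 4124, and the highest other gave 46. For genes with a 2-fold change it was 1 split, with 280 against 9, for probesets 1 split, with 25835 against 5, and for genes with unequal probesets 1 split, with 1401 against 210. For gene lists with the preset correlation 6 splits gave at least 26, and the highest other gave 27, so the count did not exclude chance. It cannot decide the question, since the other splits among the 6 kept 4 or 5 sham arrays together and held part of the real difference. Splits with 3 sham arrays on each side gave at most 12 lists. With an estimated correlation 1 split gave as many as 11 and the highest other gave 1.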

How the results depend on the processing

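The omission of infarcted replicates 4 and 5 together, and of probesets without exactly 1 symbol, was chosen only after the data were seen. The cause of the changes below was not tested, except where fewer arrays or a stricter threshold account for them. Of 4124 genes, 2266 passed at 0.01. The other alternatives gave 3123 to 5674 genes, the last with the mean over probesets, and kept between 71.1% and 97.3% of the 4124. Quantile normalization gave 1815 higher and 2653 lower. The median change of all genes was -0.04, -0.08 with centring and -0.07 with quantile normalization. Lists fell from 26 to 11 with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, called 33 (22 higher, 11 lower). Without infarcted replicates 4 and 5, probesets fell to 16744 and genes with unequal probesets to 891. Leaving out each array in turn gave 3454 to 4138 genes, 253 to 314 with a 2-fold change, 19858 to 24857 probesets, 23 to 27 lists and 1068 to 1404 genes with unequal probesets.

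A few small values changed sign. Fkbp1b was -0.13 with dim probesets left out. List means turned for endothelial markers (-0.00976 centred), skeletal muscle markers (-0.0177 without infarcted replicates 4 and 5) and T and NK cell markers (-0.0607 without dim genes, -0.0282 without dim probesets, -0.00677 centred, -0.0130 to 0.0875 with an array left out). The unfolded protein list gave -0.0286 centred, -0.0014 without infarcted replicates 4 and 5, -0.0132 with quantile normalization and -0.0244 to 0.0674 with an array left out, and Schwann cell markers -0.0176 to 0.0168. Signal near background limits what can be seen for dim genes.

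With the replicate number as a block, 3802 genes, 280 with a 2-fold change, 19085 probesets, 27 lists and 1583 genes with unequal probesets passed. The block ended the calls of Ago4 (adjusted p = 0.0694), Alas2 (0.0783), Arntl (0.0731), Dgcr8 (0.0716), Gp9 (0.0657) and Tarbp2 (0.113), while Mpo (0.0086) and the adipocyte list (0.0308) passed, and it changed no other call of a named gene or list. The data do not show that the numbers pair the samples: deviations of same-numbered arrays correlated between -0.051 and 0.10, and 2 of 6 sham arrays matched their own number best.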

Other observations

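The 6 relations between list scores were chosen only after the scores of the arrays were seen. The tendon and cartilage list was written after Comp, Fmod and Thbs4 had been seen among the largest rises, and its members were chosen before their own values were seen.

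Of 33 genes of tendon, cartilage and bone outside the 51 lists 10 rose and 1 fell, with a median of 0.07 and a mean of 0.21 (camera p = 0.0026 with the preset correlation, and p = 0.052 with an estimated one). The matrix protein gene Mgp rose by 1.15, from 11.45 ± 0.08 to 12.60 ± 0.20, Matn2 by 1.02, from 7.05 ± 0.21 to 8.07 ± 0.18, and Prg4 (lubricin) by 0.99, from 7.80 ± 0.23 to 8.79 ± 0.21 (SD, n = 6). Sox9, the transcription factor of cartilage, rose by 1.45, from 7.18 ± 0.28 to 8.62 ± 0.42 (SD, n = 6). Col2a1, the main cartilage collagen, rose by 0.38 and Runx2, of bone, by 0.37, while Cnmd fell by 0.60. The hypothesis that a tendon- or cartilage-like gene group rises in the infarcted border zone was met with the preset correlation only, and most members did not pass.

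Outside the lists and chosen after their values were seen, Angptl7 rose by 2.45 (adjusted p = 9.34e-05), Sprr1a by 2.07 (adjusted p = 1.13e-05) and Mir100hg, a host transcript of microRNAs, by 0.88 (adjusted p = 0.000151), each in 6 of 6 infarcted arrays.

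Within a group, 6 relations between list scores were computed, 3 in each group of 6 arrays. Among infarcted arrays the fatty acid oxidation score was lower where the macrophage score was higher (Pearson r = -0.87, exact permutation p = 0.021, adjusted p = 0.063; Spearman rho = -0.83, exact permutation p = 0.058, adjusted p = 0.17), and r was -0.91 without the 2 arrays farthest from the median. With the collagen score r was -0.69 (exact permutation p = 0.14, adjusted p = 0.21; rho = -0.43, exact permutation p = 0.42, adjusted p = 0.42). Neither passed the correction, so a graded response among infarcted hearts may exist but 6 arrays leave it open. Among sham arrays r was -0.35 (exact permutation p = 0.49) and -0.47 (exact permutation p = 0.35). The immediate early score and the heat shock score, whose lists share 1 gene (Atf3), moved together among sham arrays (r = 0.96, exact permutation p = 0.0042, adjusted p = 0.025; rho = 0.94, exact permutation p = 0.017, adjusted p = 0.10; r = 0.90 without the 2 farthest), a relation that passed the correction for r and not for rho. Among infarcted arrays r was 0.87 (exact permutation p = 0.033, adjusted p = 0.066; rho = 0.77, exact permutation p = 0.10, adjusted p = 0.20), which did not pass.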
